A study of Homo sapiens with 10 samples.

How the data were processed

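Ribosome footprints were measured in U2OS cells in 4 conditions. The 10 samples of the series made 6 libraries: each replicate 1 library was a single sample, and each of the other 4 libraries was a pair of sequencing lanes that the authors had combined into 1 column. Groups came from the treatment labels of the samples, and replicate numbers from the sample titles. There were 2 control and 2 Myc libraries and 1 library each for Torin-1 and for Myc with Torin-1. The dose and duration of Torin-1 were not given in the sources used here, nor was the round of the experiment to which the Torin-1 libraries belonged.

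The values were FPKM (fragments scaled by transcript length and sequencing depth) that the authors deposited in 1 table, with 1 value per gene and library. Bowtie was used for alignment, per the submitters' processing notes; its version, the genome build and the handling of reads that match several places were not given in the sources used here, so no coordinates are printed. The deposited table named a gene, a transcript and a symbol for each of 9578 rows, and the gene identifiers of 9493 rows were found in a table of gene names. Its lowest value was 1 in every library and values were given in steps of 0.1. The number of genes at that floor was 94 and 76 in the control libraries, 118 and 153 in the Myc libraries, 54 with Torin-1 and 140 with both. Depth per library could not be recovered, since values between 1.1 and 3.0 filled 20 of 20 steps in each library, so no counting interval is given. Median FPKM lay between 17.9 and 20.2 per library.

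FPKM were tested on the scale of log2(FPKM + 1), with a pseudocount of 1. A fold change is on this scale and understates the change of low genes. The 96 genes with a mean FPKM under 1.5 over the 6 libraries were left out, and 9482 were tested. The test was limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes with a trend), with 4 group means and 1 shared spread, two-sided, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Residual degrees of freedom were 2 and prior degrees of freedom 9.20. The spread came from the control and Myc groups alone, and the single Torin-1 libraries were assumed to vary like them. The Torin-1 comparison averaged the difference without Myc and the difference with Myc. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

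Before the data were examined, the samples' groups, the tests, 25 gene lists, the other settings to be tried and the rule for named genes were fixed. The rule took MYC in every library, then, for Myc and for Torin-1, the 10 largest increases and the 10 largest decreases past the threshold with the same direction in both pairs, up to 4 members of each list with the largest change, and up to 5 genes per direction for the interaction. Of the genes that this rule selects, 1 is not reported here. The further genes named in the observations belong to lists written later. The lists were cytosolic ribosomal proteins, other TOP mRNAs, ribosome biogenesis, nucleotide and polyamine synthesis, glycolysis and lactate, amino acid synthesis and ATF4 targets, aminoacyl-tRNA synthetases, sterol and fatty acid synthesis, lysosome and autophagy, extracellular matrix, TGF-beta signalling, integrins and cell adhesion, clathrin-mediated endocytosis, DNA replication, G2/M and mitosis, CDK inhibitors and p53 targets, oxidative phosphorylation, mitochondrial ribosomal proteins, chaperones, initiation factors, proteasome, histones, the Myc network, interferon response and markers of other cell types. Lists with at least 5 tested members, 24 in all, were tested with camera of limma with a preset correlation of 0.01 between genes and Benjamini-Hochberg adjustment over the lists of a comparison, and again with the correlation estimated from the libraries. The estimated correlation rests on 2 residual degrees of freedom, so that test has little power and a miss in it is weak evidence. Medians of lists were also set among 10000 random lists of the same size matched on mean FPKM in 20 bins. Such random lists do not keep the correlation between the members of a list.

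The Myc and the averaged Torin-1 comparisons share libraries. Their balance cancels the shared chance values, and 20 simulations of unchanged groups gave a mean correlation of -0.00119. These drew each gene and library independently, so the value follows from the balance. It gives no range for libraries whose genes vary together. The limma step was tested on simulated data over 9482 genes. For Myc against control, 63% of 100 genes changed 2-fold and 100% of those changed 4-fold were recovered, with 14 false calls. For the averaged Torin-1 comparison the shares were 85% and 100%, with 14 false calls. With no gene changed, the calls were 0 for Myc and 1 for Torin-1. Every simulated library, the single Torin-1 libraries included, was drawn from the fitted spread, independently for each gene. The simulation thus takes over the assumption that single libraries vary like the duplicated groups and cannot test it. Changed genes were drawn only above a minimum level, so the shares do not cover low genes.

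Alternatives were pseudocounts of 0 and 5, no filter, a filter at a mean of 10 FPKM, median-of-ratios scaling, quantile normalization, limma without a trend, the replicate number as a block, and each control or Myc library left out in turn. Models with 1 Myc term and 1 Torin-1 term, on all 6 libraries or on the 4 libraries with paired lanes, were added after seeing the data, as was the Myc network list without MYC. Footprints at single positions, translational efficiency and mRNA levels were not analysed here.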

Results

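Ribosome profiling sequences the mRNA fragments that ribosomes protect from nuclease, so that the footprints of a gene report how much of its mRNA is being translated. The libraries came from U2OS, a human osteosarcoma cell line, in which Myc, a transcription factor that drives cell growth, could be induced. Control cells and cells with Myc induced for 36 h were each represented by 2 libraries. Cells given Torin-1, an inhibitor of the mTOR kinase, and cells given both Myc induction and Torin-1 were each represented by 1 library. The values were footprint FPKM of 9578 genes per library, with a lowest value of 1. Their sums were 714163 and 752782 in the control libraries, 831871 and 748121 in the Myc libraries, 710862 with Torin-1 and 640289.5 with both. Read depth was unknown, because the table held no counts and its low values filled all 20 of the 20 possible steps between 1.1 and 3.0. The mRNA levels of these cells were not analysed here, so a footprint difference can hold a change of mRNA level, of translation, or of both.

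The first comparison asked which genes differed in footprints when Myc was induced without Torin-1. MYC (ENSG00000136997) was read at 112 and 167 FPKM in the control libraries and at 7929 and 9567 FPKM in the Myc libraries, a log2 difference of 5.98 ± 0.29 (SE, limma, n = 2 per group, Benjamini-Hochberg adjusted p = 2.39e-06), or 63.2-fold. It stood at 489 FPKM with Torin-1 and at 10918 FPKM with both treatments. Footprints of the introduced and the endogenous copy could not be separated. By a test of gene lists, the list of the extracellular matrix was lower with Myc, and those of ribosomal proteins, mitochondrial ribosomal proteins and ribosome biogenesis were higher. Each passed with a preset correlation between genes and none with an estimated one (adjusted p = 0.899 for each). Of 9482 genes tested, 2293 passed limma's test, 1109 of them higher and 1184 lower with Myc, and the difference exceeded 2-fold in 480 and 686 of these.

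**Figure D1:**
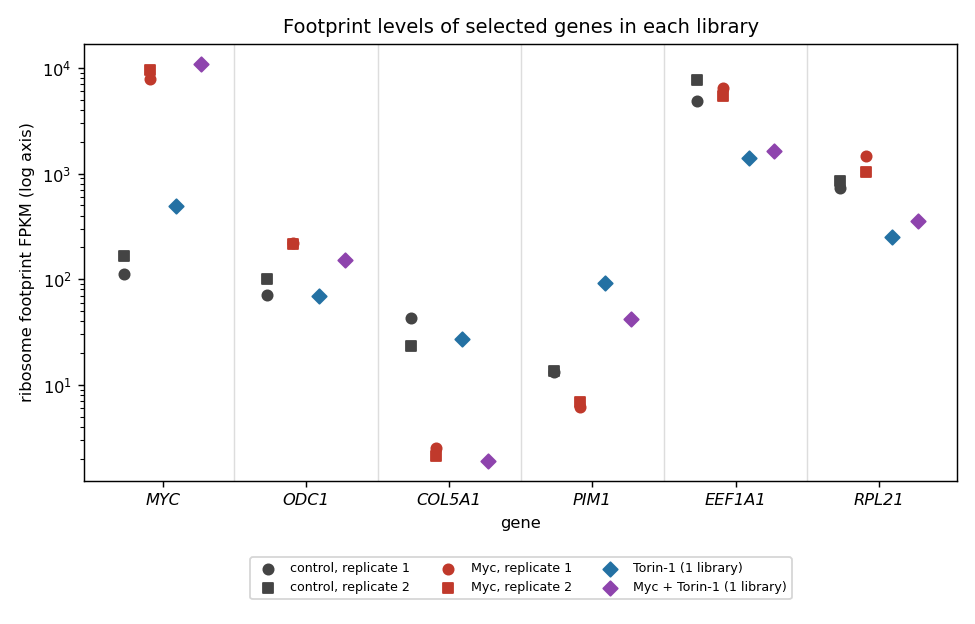
Footprint FPKM (log axis) of 6 genes in each of the 6 libraries, 1 point per library, with circles and squares for replicates 1 and 2 and diamonds for the single Torin-1 libraries. MYC rose from 112 and 167 FPKM to 7929 and 9567 FPKM with Myc, COL5A1 fell to 2.5 and 2.1 FPKM, and EEF1A1 stood at 1392 and 1651 FPKM in the Torin-1 libraries.

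MYC had the largest increase with Myc. CAMKV, which encodes a kinase-like vesicle protein, was at the floor of 1 FPKM in both control libraries and averaged 19.45 FPKM with Myc. HES7, a transcriptional repressor of the somite clock, and PDE1B, a cyclic nucleotide phosphodiesterase, were also at the floor in both control libraries and averaged 11.5 and 9.85 FPKM with Myc. INSL4, an insulin-like peptide, rose from 4.30 ± 2.40 to 42.9 ± 17.7 FPKM (SD, n = 2), and RGS16, a regulator of G protein signalling, from 10.05 ± 2.90 to 89.7 ± 10.7 FPKM. GABRA5, a GABA receptor subunit, KIF9, a kinesin, DNAJC12, a co-chaperone, and ADCYAP1R1, the receptor of the neuropeptide PACAP, completed the 10, with log2 differences of 2.46, 2.29, 2.23 and 2.20.

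Of the 10 genes with the largest decreases with Myc, CLDN4, a tight junction protein, fell from 157 ± 69.4 to 6.05 ± 3.18 FPKM (SD, n = 2), a log2 difference of -4.50 ± 0.36 (SE, limma, Benjamini-Hochberg adjusted p = 0.000115). HAPLN1, which links hyaluronan to proteoglycans, and LOXL4 and LOXL2, which crosslink collagen, had log2 differences of -4.03, -3.90 and -3.06. For IGFBP5, a binding protein of insulin-like growth factors, the log2 difference was -3.89, for OLFML3, a secreted matrix protein, -3.76, for COL5A1, a collagen chain, -3.31, for ODZ2, a teneurin, -3.05, and for RNASE1, a secreted ribonuclease, -3.05. Some control pairs differed widely, so the size of these falls is uncertain. IGFBP5 was read at 108.7 and 13.5 FPKM in the control libraries, HAPLN1 at 347.7 and 115 FPKM and LOXL4 at 187.4 and 58.5 FPKM. With Myc, IGFBP5 was read at 2.6 FPKM and at the floor. EDN2, an endothelin, averaged 19.6 FPKM in control cells and was at the floor in both Myc libraries.

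Among 33 tested genes of the extracellular matrix, 24 fell and 0 rose with Myc (28 and 0 when adjusted over the list alone), with a median log2 difference of -1.65. COL1A1 fell from 211 ± 15.2 to 29.4 ± 0.71 FPKM (SD, n = 2), and the laminin chain LAMB2 fell by 2.71 on the log2 scale. The list passed camera, limma's test of a list against other genes, at an adjusted p of 1.72e-14 with a preset correlation between genes, and missed it with adjusted p = 0.899 with an estimated correlation. Of 27 genes for integrins and cell adhesion, 16 fell and 0 rose (20 and 0 when adjusted over the list alone; median -0.92), among them ITGA3 at -2.33, L1CAM at -2.54, NCAM1 at -2.22 and ITGA7 at -2.13 on the log2 scale (camera adjusted p = 4.43e-08, and adjusted p = 0.579 with an estimated correlation). Of 29 genes of TGF-beta signalling, 13 fell and 1 rose (13 and 1 when adjusted over the list alone; median -0.52). The tropomyosin TPM1 fell by 2.03 on the log2 scale (camera adjusted p = 8.16e-05 for the list, and adjusted p = 0.579 with an estimated correlation).

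Genes of lysosomes and autophagy were also lower with Myc, with 15 of 41 fallen and 2 risen (18 and 4 when adjusted over the list alone; median -0.58, and -0.91 without Myc replicate 1; camera adjusted p = 9.82e-05, and adjusted p = 0.899 with an estimated correlation). GPNMB, a lysosomal glycoprotein, had a log2 difference of -2.63, NPC2, a cholesterol carrier of the lysosome, -2.18, ARSA -1.92 and the cathepsin CTSB -1.67. Of 29 genes of sterol and fatty acid synthesis, 6 fell and 0 rose (3 and 0 when adjusted over the list alone; median -0.56, and -0.37 without Myc replicate 2; camera adjusted p = 3.71e-05, and adjusted p = 0.899 with an estimated correlation), including SREBF2, a transcription factor of cholesterol synthesis, which fell by 1.35 on the log2 scale. Of 28 genes of G2/M and mitosis, 7 fell and 0 rose (7 and 0 when adjusted over the list alone; median -0.46; camera adjusted p = 0.000191, and adjusted p = 0.899 with an estimated correlation). That median was -0.25 in the replicate 1 pair, -0.61 in the replicate 2 pair and -0.27 without Myc replicate 2. ANLN fell by 1.42 on the log2 scale, and TOP2A, which untangles DNA, fell by 1.39. Of 10 interferon response genes, 5 fell and 0 rose (7 and 0 when adjusted over the list alone; median -0.91; camera adjusted p = 0.00358, and adjusted p = 0.651 with an estimated correlation), and this list also missed camera's threshold when only genes averaging at least 10 FPKM were tested (median -0.35, adjusted p = 0.419). Its median was -0.58 with a pseudocount of 5.

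Lists of ribosomal proteins, mitochondrial ribosomal proteins and ribosome biogenesis had positive medians with Myc, with a minority of members past the test. Of 78 cytosolic ribosomal protein genes, 12 rose and 0 fell (0 and 0 when adjusted over the list alone), with a median log2 difference of 0.65, which was 0.94 in the replicate 1 pair, 0.30 in the replicate 2 pair and 0.42 without control replicate 1 (camera adjusted p = 3.73e-08, and adjusted p = 0.899 with an estimated correlation). RPLP1 rose by 0.98, RPL39 by 0.97, RPS12 by 0.94 and RPL22 by 0.94 on the log2 scale. Of 73 mitochondrial ribosomal protein genes, 20 rose and 0 fell (26 and 0 when adjusted over the list alone; median 0.58; camera adjusted p = 4.43e-08, and adjusted p = 0.899 with an estimated correlation), with MRPL21 at 1.31 and MRPL50 at 1.14. The mitochondrial median was 0.26 in the model with 1 Myc term when both replicate 1 libraries were left out. Of 45 ribosome biogenesis genes, 15 rose and 0 fell (15 and 0 when adjusted over the list alone; median 0.49, 0.80 in the replicate 1 pair and 0.15 in the replicate 2 pair; camera adjusted p = 1.01e-05, and adjusted p = 0.899 with an estimated correlation). PNO1 and RRP9, which act in small subunit assembly, rose by 1.62 and 1.55 on the log2 scale, and LYAR and NOP16 by 1.44 and 1.23.

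Of 73 genes of oxidative phosphorylation, 6 rose and 0 fell with Myc (4 and 0 when adjusted over the list alone; median 0.38; camera adjusted p = 0.00134, and adjusted p = 0.899 with an estimated correlation). UQCRH, a subunit of complex III, rose by 1.45 and CYCS, cytochrome c, by 1.26 on the log2 scale. That list missed the threshold when the libraries of all 4 groups shared 1 Myc term (median 0.23, adjusted p = 0.0827) and when both replicate 1 libraries were left out of that model (median 0.04, adjusted p = 0.458). Of 33 initiation factor genes, 5 rose and 1 fell (4 and 1 when adjusted over the list alone; median 0.40; camera adjusted p = 0.0129, and adjusted p = 0.899 with an estimated correlation), with EIF3J at 1.58 and the cap-binding protein EIF4E at 1.05. Without Myc replicate 1 this list's adjusted p was 0.0515, and without both replicate 1 libraries its median was 0.25. Of 11 Myc network genes, MYC itself included, 5 rose and 2 fell (5 and 2 when adjusted over the list alone; median 0.61; camera adjusted p = 0.0279, and adjusted p = 0.899 with an estimated correlation). With MYC, the induced gene, left out of the list, 4 of 10 rose and 2 fell, and the list missed the threshold (median 0.50, adjusted p = 0.165). MAX, the partner of Myc, averaged 48.0 FPKM in control and 129.8 FPKM in Myc libraries, and MXD3, a Myc antagonist, 18.1 and 2.20 FPKM. Without Myc replicate 2 the network list's adjusted p was 0.230, and 0.226 when only genes averaging at least 10 FPKM were tested.

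The remaining lists did not pass camera for Myc, although single members did. Of 29 genes of amino acid synthesis and ATF4 targets, 6 rose and 2 fell (6 and 2 when adjusted over the list alone), and the stress transcription factors DDIT3 and ATF4 rose by 2.03 and 1.59 on the log2 scale. Of 29 nucleotide and polyamine synthesis genes, 5 rose and 6 fell (7 and 6 when adjusted over the list alone). ODC1, the rate-limiting enzyme of polyamine synthesis, rose from 85.2 ± 20.1 to 217 ± 2.90 FPKM (SD, n = 2), IMPDH1 rose by 1.51 on the log2 scale, and the ribonucleotide reductase subunit RRM1 fell by 1.15. Of 37 DNA replication genes, 5 rose and 6 fell (5 and 6 when adjusted over the list alone), with the phosphatase CDC25A at 1.03, the polymerase subunit POLA2 at -1.03 and the cyclins CCNE1 and CCND1 at 0.99 and 0.95. Of 19 glycolysis genes, 2 rose and 4 fell (2 and 4 when adjusted over the list alone), with the hexokinase HK2 at 1.09 and the aldolase ALDOC at -1.09. Of 20 CDK inhibitor and p53 target genes, 1 rose and 2 fell (1 and 2 when adjusted over the list alone), and the cell cycle inhibitor CDKN1B fell by 1.31. Of 31 genes of clathrin-mediated endocytosis, 0 rose and 4 fell (0 and 4 when adjusted over the list alone), with the adaptor subunit AP2A1 at -1.54 and the clathrin heavy chain CLTC at -1.42. Of 29 chaperone genes, 3 rose and 1 fell (3 and 1 when adjusted over the list alone). Those were HSPE1, the near-identical pair HSPA1A and HSPA1B, whose values are uncertain, and, downward, PDIA4. Of 22 other TOP mRNAs, whose translation depends on a 5' pyrimidine tract, 2 rose and 1 fell (0 and 1 when adjusted over the list alone), of 22 aminoacyl-tRNA synthetase genes 0 and 2 (0 and 1 when adjusted over the list alone), and 0 of 31 proteasome and 0 of 8 histone genes passed in either direction (0 when adjusted over the list alone). Of the markers of other cell types, SYP and ACTA1 were measured, at -0.11 and -0.52, neither past the test.

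In all, 13 of 24 tested lists passed camera for Myc with the preset correlation and 0 with an estimated one. With the latter the smallest adjusted p was 0.579 and 2 lists had an unadjusted p under 0.05. The estimated correlation was 0.0129 for integrins and 0.0068 for TGF-beta signalling, near the preset 0.01, and -0.071 for interferon response. Their camera adjusted p still rose to 0.579, 0.579 and 0.651. Missing the threshold with an estimated correlation therefore does not by itself show that members of a list vary together. Leaving out control replicate 1, control replicate 2, Myc replicate 1 or Myc replicate 2 left 0 genes past limma's test each time, with 1546 to 2839 genes at an unadjusted p under 0.05, and every tested gene of the 2293 kept its direction in each of these fits. The count was 3743 in a model with 1 Myc and 1 Torin-1 term on all 6 libraries and 3519 in that model on the 4 libraries with paired lanes. The 2293 genes were selected with these same libraries, so that keeping their direction was largely fixed by the selection. The labels do not say whether replicates came from separate cultures, so p-values here measure the spread between these libraries, which may be technical.

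The second comparison asked how footprints differed with Torin-1, averaged over cells without and with Myc. Lists of ribosomal proteins and other TOP mRNAs were lower by camera with a preset correlation and not with an estimated one (adjusted p = 0.762 for each). PIM1, a serine/threonine kinase, was read at 13.35 ± 0.071 FPKM in control cells (SD, n = 2) and 92.9 FPKM with Torin-1, and at 6.55 ± 0.49 FPKM with Myc and 41.9 FPKM with both (log2 difference 2.61 ± 0.20, SE, limma, Benjamini-Hochberg adjusted p = 0.000334). EEF1A1, the elongation factor that brings aminoacyl-tRNA to the ribosome, fell by 1.99 ± 0.27 on the log2 scale (limma, Benjamini-Hochberg adjusted p = 0.00531). Of 9482 genes, 348 passed limma's test, 261 of them higher and 87 lower, and the difference exceeded 2-fold in 149 and 62.

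The other 9 of the 10 largest increases with Torin-1 were C8orf4, DUSP1, CITED2, KLF6, GEM, ID2, BHLHE40, DUSP5 and GADD45A, with log2 differences of 2.93, 2.41, 2.32, 2.25, 2.19, 2.18, 2.17, 2.15 and 2.14. DUSP1 and DUSP5 are MAP kinase phosphatases, KLF6, CITED2, ID2 and BHLHE40 regulate transcription, GEM is a small GTPase, and GADD45A is a stress-induced growth arrest gene. DUSP1 was read at 230.6 FPKM with Torin-1 and 231.6 FPKM with both, against 55.1 ± 15.8 FPKM in control and 33.6 ± 4.88 FPKM in Myc libraries (SD, n = 2). After EEF1A1, the largest decreases were in the ribosomal protein genes RPL21, RPL17, RPS2, RPS18, RPL10 and RPSA, from -1.71 to -1.44, the elongation factor gene EEF1G at -1.48, CRTAP, a collagen-modifying protein, at -1.49, and CSTA, a protease inhibitor, at -1.49. Ribosomal protein genes and EEF1A1 have near-identical pseudogene copies, and how shared reads were counted was not given in the sources used here, so their single values are uncertain.

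Of the 87 genes that fell with Torin-1, 41 were cytosolic ribosomal protein genes, 7 were other TOP mRNAs and 39 were neither. The 41 were among 78 ribosomal protein genes tested, of which 0 rose (69 and 0 when adjusted over the list alone), with a median log2 difference of -0.99. That list passed camera at an adjusted p of 6.14e-42, and missed it with adjusted p = 0.762 with an estimated correlation. Measured against replicate 2 alone, the median was -1.08 without Myc and -1.03 with Myc. Measured against replicate 1 alone it was -0.60 and -1.13. After quantile normalization the averaged median was -0.62. Of 22 other TOP mRNAs, 7 fell and 0 rose (18 and 0 when adjusted over the list alone; median -0.86; camera adjusted p = 6.78e-16, and adjusted p = 0.762 with an estimated correlation). EIF3F fell by 1.24 on the log2 scale, and GNB2L1, a ribosome-bound scaffold protein, fell by 1.08. Genes of ribosome biogenesis, whose list was higher with Myc, had a median of 0.13 with Torin-1, and 0 of 45 passed the test (0 when adjusted over the list alone). That median was 0.0408 without control replicate 1, 0.25 without control replicate 2 and 0.0276 against replicate 2 alone.

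Genes of TGF-beta signalling and of the Myc network were the lists higher with Torin-1. Of 29 genes of TGF-beta signalling, 5 rose and 0 fell (11 and 0 when adjusted over the list alone; median 0.27; camera adjusted p = 0.00211, and adjusted p = 0.762 with an estimated correlation). Besides ID2, an inhibitor of differentiation, INHBA, a subunit of activin, and CTGF, a matricellular growth factor, rose by 1.94 and 1.76 on the log2 scale. Without control replicate 2 this list's adjusted p was 0.0516. Of 11 Myc network genes, 3 rose and 0 fell (5 and 0 when adjusted over the list alone; median 0.56; camera adjusted p = 8.6e-05, and adjusted p = 0.762 with an estimated correlation). With MYC left out of the list its camera adjusted p was 0.000371. The 3 were MYC at 1.08 and the antagonists MXD3 and MXD1 at 0.99 and 0.93. Of 20 CDK inhibitor and p53 target genes, 5 rose and 0 fell (6 and 2 when adjusted over the list alone), among them GADD45B at 1.85, CDKN1B at 1.52 and PMAIP1, a pro-apoptotic BCL2 family member, at 1.29, while the list itself did not pass camera (adjusted p = 0.0905). CEBPB and DDIT3, of the ATF4 list, rose by 1.48 and 1.44, the autophagy kinase ULK1 by 0.91 and the proliferation marker MKI67 by 0.89 on the log2 scale. Of the markers of other cell types, the muscle actin ACTA1 fell by 1.09 and SYP stood at -0.16.

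Further lists were lower with Torin-1 by small amounts, with few or no single genes past the test. Chaperones had a median of -0.38 (camera adjusted p = 1.23e-05, and adjusted p = 0.762 with an estimated correlation), with 1 of 29 genes fallen, HSPA8 at -1.13 (1 when adjusted over the list alone). Sterol and fatty acid synthesis had a median of -0.31 (camera adjusted p = 0.00108) with 0 of 29 genes past the test (0 when adjusted over the list alone), and nucleotide and polyamine synthesis -0.23 (camera adjusted p = 0.00353) with 0 of 29 (0 when adjusted over the list alone). Both had adjusted p = 0.762 with an estimated correlation. Without Myc replicate 1 the medians of chaperones, sterol synthesis and nucleotide synthesis were -0.21, -0.19 and -0.11. After quantile normalization those of chaperones and sterol synthesis were -0.19 and -0.0974 (camera adjusted p = 0.0418 for both). Extracellular matrix genes had a median of -0.40 (camera adjusted p = 6.31e-05, and adjusted p = 0.762 with an estimated correlation), with 0 of 33 past the test (0 when adjusted over the list alone). Without Myc replicate 1 this median was -0.22, measured against replicate 2 alone it was -0.0044, and in the model without both replicate 1 libraries the list missed the threshold (adjusted p = 0.374). The medians of these 4 lists lay at the 0.81, 0.22, 1.19 and 0 percentiles of 10000 random lists matched on mean FPKM. For oxidative phosphorylation (median -0.18), mitochondrial ribosomal proteins (-0.11), proteasome (-0.23), glycolysis (-0.23) and aminoacyl-tRNA synthetases (-0.19), the camera adjusted p was 0.00019, 0.00353, 0.000914, 0.00353 and 0.00504, with adjusted p = 0.762 with an estimated correlation for each. Their medians lay between the 11.1 and 40.6 percentiles of matched random lists. Single members past the test in these 5 lists came to 1, the synthetase QARS, which fell by 1.16 on the log2 scale (2 when adjusted over each list alone, with 1 in the glycolysis list). Without Myc replicate 1 the medians of proteasome, glycolysis and mitochondrial ribosomal proteins were -0.14, -0.0875 and -0.0641. Without control replicate 2 that of oxidative phosphorylation was -0.11. Mitochondrial ribosomal proteins had a median of -0.20 without control replicate 1 and -0.17 without Myc replicate 2, and the synthetases -0.32 without Myc replicate 2. Mitochondrial ribosomal proteins missed camera's threshold without control replicate 2 (median -0.0249, adjusted p = 0.0641) and the synthetases without Myc replicate 1 (median -0.0471, adjusted p = 0.0583), and all 5 missed it after quantile normalization.

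**Figure D2:**
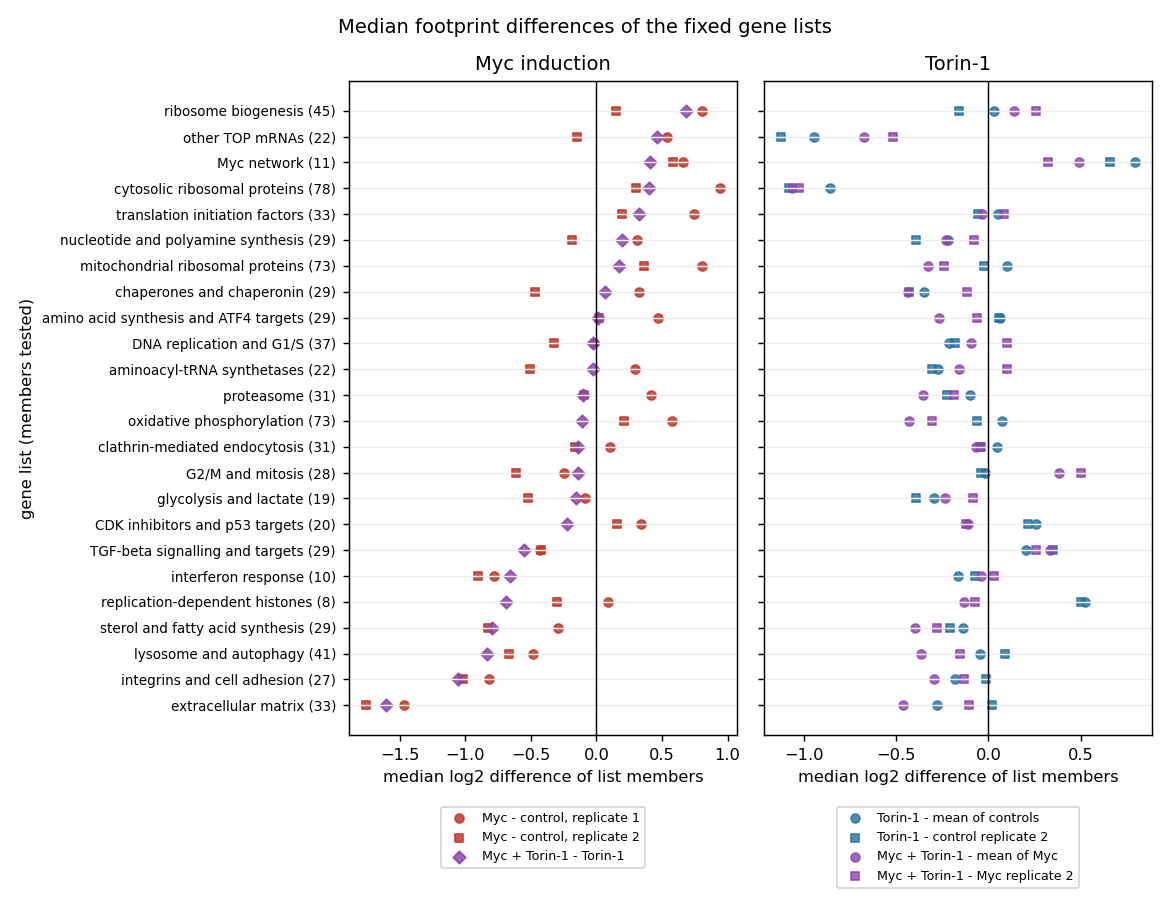
Median log2 difference in FPKM of the members of each gene list (rows, with the number of tested members), for Myc induction (left) and Torin-1 (right), 1 point per pairing of libraries or group means. Ribosomal protein genes lie at 0.94 and 0.30 in the Myc pairs and between -0.86 and -1.08 in the 4 Torin-1 pairings drawn. Pairings with replicate 1 alone (-0.60 and -1.13) are not drawn. Extracellular matrix genes lie at -1.47 and -1.75 with Myc.

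In all, 13 of 24 lists passed camera for Torin-1 (lysosome, integrin, clathrin, DNA replication, G2/M, ATF4, initiation factor, histone and interferon genes were among those that did not) with the preset correlation and 0 with an estimated one, where 0 lists had an unadjusted p under 0.05. Each Torin-1 group was a single library, assumed to vary like the duplicated groups, and leaving out control replicate 1, control replicate 2, Myc replicate 1 or Myc replicate 2 left 0 genes past limma's test (886 to 2216 at an unadjusted p under 0.05). The count was 172 after median-of-ratios scaling (102 higher, 70 lower), 101 after quantile normalization (72 higher, 29 lower) and 28 without the filter on low values (27 higher, 1 lower). It was 752 in the model with 1 Myc and 1 Torin-1 term on all 6 libraries and 568 in that model on the 4 libraries with paired lanes. Taken singly, Torin-1 against control gave 26 genes (24 higher, 2 lower) and both treatments against Myc alone gave 41 (37 higher, 4 lower).

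The third comparison asked what Myc induction changed in cells given Torin-1, with 1 library on each side. The lists of extracellular matrix and ribosome biogenesis passed camera here as well, the first lower and the second higher, with a preset correlation and not with an estimated one (adjusted p = 0.896 for each). Of 33 matrix genes, 19 fell and 0 rose (23 and 0 when adjusted over the list alone; median -1.60, at the 0 percentile of matched random lists; camera adjusted p = 7.58e-14, and adjusted p = 0.896 with an estimated correlation), with COL5A1 at -3.28 and LAMB2 at -2.57 on the log2 scale. All 45 ribosome biogenesis genes had a positive difference, with 2 past the test (2 when adjusted over the list alone), RRP1B at 1.49 and DDX10 at 1.42, and a median of 0.68 (camera adjusted p = 3.95e-09, and adjusted p = 0.896 with an estimated correlation). Of 9482 genes, 697 passed limma's test, 177 higher and 520 lower, on the assumption that these single libraries vary like the duplicated groups.

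Integrins and cell adhesion genes (7 of 27 fallen, 16 when adjusted over the list alone; median -1.06; camera adjusted p = 1.8e-07) included the caveolin CAV1, which fell by 2.49 on the log2 scale; this list had adjusted p = 0.716 with an estimated correlation. Lysosome genes (8 of 41 fallen, 13 when adjusted over the list alone; median -0.83; camera adjusted p = 3.1e-06) included GPNMB and NPC2 at -2.74 and -2.29, and sterol synthesis genes (3 of 29 fallen, 9 when adjusted over the list alone; median -0.79; camera adjusted p = 2.68e-06) included INSIG1, which fell by 1.39. Both had adjusted p = 0.896 with an estimated correlation. In TGF-beta signalling 3 of 29 genes fell and 1 rose (10 and 1 when adjusted over the list alone; median -0.55; camera adjusted p = 0.00235, and adjusted p = 0.716 with an estimated correlation), with the transcription factor SNAI1 at 1.66. Histones (1 of 8 fallen, 4 when adjusted over the list alone; median -0.69) and interferon response genes (1 of 10 fallen, 2 when adjusted over the list alone; median -0.66) each had a camera adjusted p of 0.0245, and adjusted p = 0.716 with an estimated correlation. Ribosomal proteins (median 0.40, camera adjusted p = 1.2e-05), other TOP mRNAs (median 0.46, 0.00281) and initiation factors (median 0.33, 0.00978) were higher, each with adjusted p = 0.931 with an estimated correlation. After quantile normalization the medians of ribosomal proteins and initiation factors were 0.64 and 0.50. Single genes past the test in these 3 lists came to 1, EIF3J, which rose by 1.44 (0 when adjusted over each list alone).

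The Myc effects without and with Torin-1 rested on different libraries, and were correlated across 9482 genes, which are not independent replicates (Pearson's r = 0.827, Spearman's rho = 0.775). The correlation was 0.785 for the replicate 1 pair and 0.816 for the replicate 2 pair, and 0.827 with MYC left out. Of 1109 genes higher with Myc, 1077 (97.1%) had a positive difference under Torin-1 and 137 passed the test there (20.7 for independent lists). Of 1184 genes lower with Myc, 1165 (98.4%) had a negative difference under Torin-1 and 476 passed (64.9 for independent lists). Both tests used the same spread for each gene, so a gene with a small spread passes both more easily. The values for independent lists are therefore no measure of chance. Leaving out control replicate 1, control replicate 2, Myc replicate 1 or Myc replicate 2, which supply the spread, left 0 genes past limma's test for Myc under Torin-1 (1593 to 2207 at an unadjusted p under 0.05), and without the filter on low values 315 passed.

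**Figure D3:**
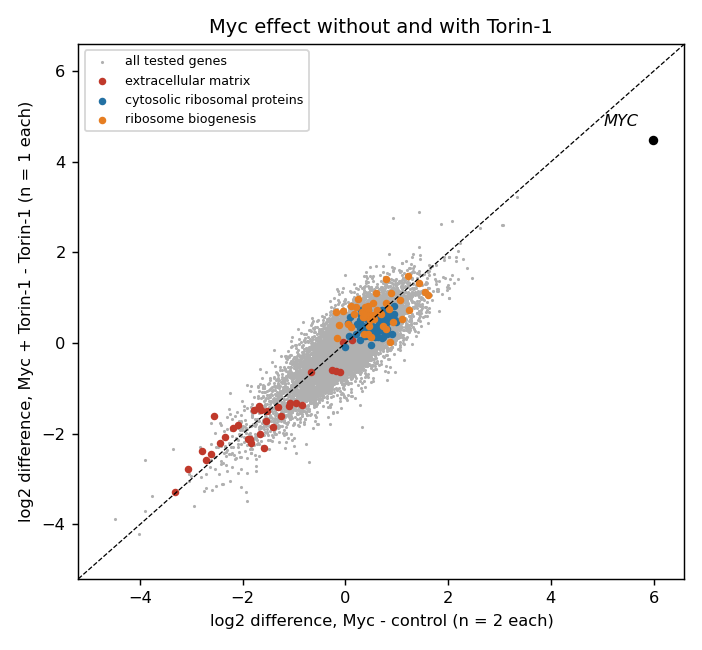
Log2 difference of each of 9482 genes with Myc under Torin-1 (y axis, 1 library per group) against that without Torin-1 (x axis, 2 libraries per group), 1 point per gene, with the dashed line marking equal differences. The relation had a Pearson's r of 0.827, extracellular matrix genes lie at the lower left (medians -1.60 and -1.65) and ribosome biogenesis genes at the upper right (medians 0.68 and 0.49).

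The last comparison asked whether the Myc effect differed with Torin-1. The genes that led it were EGR1, an immediate-early transcription factor, at 24.1 ± 6.86 FPKM in control, 47.6 ± 18.4 FPKM in Myc (SD, n = 2), 4.4 FPKM in Torin-1 and 35.8 FPKM in both, ARID4B, G2E3, JHDM1D and PHF20 upward, and TMEM25, NMNAT1, RHEBL1, PDK3 and NUPR1 downward. None of these passed the test, and 0 of 9482 genes did (smallest limma Benjamini-Hochberg adjusted p = 0.972, with 252 genes at an unadjusted p under 0.05). MYC itself had a difference of -1.50 ± 0.50 (SE), not past the test. Among the lists, 7 of 24 passed camera and 0 with an estimated correlation (adjusted p = 0.937 with an estimated correlation for each of the 7): oxidative phosphorylation, mitochondrial ribosomal proteins and histones downward, and G2/M and mitosis, other TOP mRNAs, DNA replication and ribosome biogenesis upward. Genes of oxidative phosphorylation had a median Myc effect of 0.38 without and -0.11 with Torin-1, and genes of G2/M and mitosis -0.46 and -0.14. The median of all genes in this comparison was -0.12, and was -0.02 after median-of-ratios scaling and -0.01 after quantile normalization, a shift of 0.10 and 0.11, against which these list values have to be read. The baseline also varied with expression. Sterol synthesis at -0.30 and lysosome genes at -0.25, which did not pass, lay at the 49.3 and 58.0 percentiles of matched random lists. Part of a negative list median can thus be shared by other genes of similar mean FPKM. For the lists of extracellular matrix, nucleotide synthesis, TGF-beta signalling, integrins, clathrin-mediated endocytosis, chaperones and initiation factors, which did not pass, the median was below 0 while camera gave an upward direction. Median, mean and camera direction also differed in sign for clathrin-mediated endocytosis with Torin-1 and, for Myc under Torin-1, for aminoacyl-tRNA synthetases, DNA replication, chaperones and the ATF4 list, none past the threshold.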

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

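The tests against replicate 2 alone in this part were chosen only after the results were seen. Each item is a gene list whose median Myc effect differed with and without Torin-1, by camera on the interaction with a preset correlation. All rest on 1 pair of Torin-1 libraries, and each had adjusted p = 0.937 with an estimated correlation.

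Genes of oxidative phosphorylation had a median difference of the Myc effects of -0.5176 (camera adjusted p = 2.11e-07), negative for 67 of 73 genes, among which NDUFB1 and NDUFC1 stood at -1.11 and -1.06. Mitochondrial ribosomal proteins had -0.4053 (camera adjusted p = 2.39e-06), negative for 72 of 73 genes. Negative values were common in this comparison. Sterol synthesis at -0.30 and lysosome genes at -0.25 lay at the 49.3 and 58.0 percentiles of matched random lists, so part of these 2 medians can be shared by other genes. Genes of G2/M and mitosis had 0.3674 (camera adjusted p = 1.77e-05), positive for 20 of 28, with TOP2A at 1.25 and MKI67 at 1.17. Its median was 0.18 without Myc replicate 2. After quantile normalization the medians of oxidative phosphorylation and mitochondrial ribosomal proteins were -0.21 and -0.15 (adjusted p = 0.00222 and 0.00316). The replicate 1 libraries, which had 1 lane each, might account for such differences, since the Torin-1 libraries resembled replicate 2 in having paired lanes. With replicate 2 alone as the comparison, the median for oxidative phosphorylation was -0.33, at the 0.4 percentile of random lists matched on expression. That for G2/M was 0.42, above 100% of them, so neither difference vanished without the replicate 1 libraries. Random lists do not keep the correlation between members, estimated at 0.56 and 0.40 for these lists. Lists that did not pass reached similar values with replicate 2 alone, from 0.49 for aminoacyl-tRNA synthetases to -0.30 for CDK inhibitors and p53 targets. The percentiles thus do not measure chance variation of the libraries. For mitochondrial ribosomal proteins the median with replicate 2 alone was -0.19, at the 43.22 percentile, so that a difference of the replicate 1 libraries stays open there. A difference in the response to Myc when mTOR is inhibited also stays open for each list, as does chance variation of the single Torin-1 libraries and of the replicate 2 libraries.

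The median difference was 0.2443 for other TOP mRNAs (camera adjusted p = 0.00115), 0.58 with replicate 2 alone, and without control replicate 2 it was 0.0391 (adjusted p = 0.0966). Without Myc replicate 2 it was 0.0875, without control replicate 1 0.41 and without Myc replicate 1 0.41. It was 0.2086 for ribosome biogenesis (camera adjusted p = 0.0173), 0.49 with replicate 2 alone, 0.34 without control replicate 1, -0.0165 without control replicate 2 (adjusted p = 0.652) and 0.0014 without Myc replicate 2 (adjusted p = 0.101). For DNA replication and G1/S it was 0.1255 (camera adjusted p = 0.00608), 0.41 with replicate 2 alone, 0.34 without Myc replicate 1 and 0.0559 without Myc replicate 2 (adjusted p = 0.129). For the 8 histone genes it was -0.6328 (camera adjusted p = 0.00549), negative for 8 of 8, -0.54 with replicate 2 alone, and -0.19 after quantile normalization (adjusted p = 0.132).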

How the results depend on the processing

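The models with 1 Myc and 1 Torin-1 term, and the Myc network list without MYC, were chosen after the results were seen, and the other alternatives were fixed before the data were examined. The 2293 genes for Myc stayed within 1.5 times that count under both pseudocounts, both filters, both scalings and without a trend, and became 3871 with the replicate block (2037 higher, 1834 lower), 3743 in the model with 1 Myc term on all 6 libraries, 4403 in that model with the replicate block and the Torin-1 libraries placed with replicate 2, and 3519 on the 4 libraries with paired lanes (1413 higher, 2106 lower). The 348 genes for Torin-1 became 28 without the filter, 172 after median-of-ratios scaling, 101 after quantile normalization, 752 in the model with 1 term on all 6 libraries and 568 on the 4 libraries with paired lanes. The 697 for Myc under Torin-1 became 315 without the filter, with 35.8% higher after quantile normalization against 25.4% as deposited. Without the filter the prior degrees of freedom were 5.10 rather than 9.20. They were infinite in the fits with a block or on 4 libraries, which take the spread to be the same for all genes of a level, so their counts depend on that assumption. They were 21.6 in the model with 1 Myc and 1 Torin-1 term on all 6 libraries, whose counts were larger too. The cause of these changes in count was not tested. The interaction had 0 genes past limma's test under every alternative fitted to it, left-out libraries included (62 to 376 at an unadjusted p under 0.05).

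Leaving out 1 of the 4 control and Myc libraries gave 0 genes for Myc, for Torin-1 and for Myc under Torin-1, with 1 residual degree of freedom and 2.35 to 2.86 prior degrees of freedom, and the correlation of the Myc effects ranged from 0.782 to 0.815. All 348 Torin-1 genes kept their direction against replicate 2 alone, but they were selected by a fit that held these libraries, so this was largely fixed by the selection. The control and Myc libraries of the same number deviated together (r = 0.510 across genes), but with 2 pairs the number is not taken to pair them, and the labels place the Torin-1 libraries in no round, so the replicate block with group means was run for Myc alone. Placing the Torin-1 libraries with replicate 2 was an assumption, under which the model with 1 Torin-1 term and the block gave 488 genes for Torin-1 (357 higher, 131 lower).

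With an estimated correlation, which rests on 2 residual degrees of freedom, 0 lists passed for Myc, Torin-1, Myc under Torin-1 and the interaction. The interaction lists numbered 13 after quantile normalization and 8 to 11 without 1 library. Of the lists past camera, 0 of 13 for Myc, 0 of 13 for Torin-1 and 1 of 7 in the interaction had a median of the other sign without 1 library. Of the lists not past it, 7 of 11, 3 of 11 and 10 of 17 did. A change of sign in a list past camera before or after it occurred only in the interaction. After quantile normalization these were ribosomal proteins (0.147), nucleotide synthesis (0.241), chaperones (0.258) and initiation factors (0.122), where the shift of the median of all genes is part of the change. Without 1 library the interaction ranges were -0.0165 to 0.342 for ribosome biogenesis, -0.184 to 0.273 for nucleotide synthesis, -0.464 to 0.285 for extracellular matrix, -0.315 to 0.317 for chaperones, -0.237 to 0.422 for aminoacyl-tRNA synthetases, -0.116 to 0.276 for glycolysis, -0.234 to 0.242 for interferon response, -0.321 to 0.106 for the Myc network, -0.350 to 0.0946 for initiation factors and -0.171 to 0.0899 for clathrin-mediated endocytosis, which cross 0, and 0.00507 to 0.179 for TGF-beta signalling. Over the named genes past the test, 1566 values under alternatives other than a left-out library stayed past it and 103 did not, and none reversed. Depth was unknown, so its limit on low genes could not be computed.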

Other observations

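The tests in this part were prompted by results already seen, and that of ribosomal proteins against replicate 2 alone was chosen after its own result was seen. For the other tests, the predictions were written before the values that they measure were seen. A number of genes moved with both Myc and Torin-1. CDKN1B, which encodes the cell cycle inhibitor p27, fell by 1.31 on the log2 scale with Myc and rose by 1.52 with Torin-1, and MXD3 fell by 2.61 and rose by 0.99. DDIT3, by contrast, rose with each, at 2.90 FPKM in control, 15.3 FPKM in Myc, 12.1 FPKM in Torin-1 and 33.7 FPKM in both. Of 261 genes higher with Torin-1, 69 were also higher with Myc (30.5 for independent lists) and 24 lower (32.6). Here too both tests used the same spread for each gene, so the values for independent lists are no measure of chance. Across 9482 genes the Myc and averaged Torin-1 differences had r = 0.198 and a covariance of 0.0572, against a mean of -6.36e-05 in 20 simulations of unchanged groups. Those simulations drew genes independently, whereas the replicate 1 libraries deviated together across genes (r = 0.510). They therefore cannot show whether the correlation exceeds chance.

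From the genes that rose with Torin-1, 2 hypotheses were drawn and tested with lists written before their values were seen. One was that targets of FOXO transcription factors, which mTOR and AKT signalling restrain, rose. Of 17 tested FOXO targets, 3 rose (FBXO32 by 1.43, HBP1 by 1.28 and BCL2L11 by 1.09 on the log2 scale) and 0 fell, and 13 were positive. Their median was 0.48, and it lay at least at the 99.41 percentile of matched random lists both without and with Myc. Against replicate 2 alone the median was 0.32 without Myc and 0.51 with Myc. In the averaged comparison, some lists that did not pass camera lay at similar percentiles. Ribosome biogenesis was at the 99.77 percentile, G2/M and mitosis at 99.75 and initiation factors at 99.11. Such a percentile thus does not by itself mark a risen list. The FOXO list was not among those tested with camera. The other hypothesis was that mRNAs with short half-lives rose, as they might when their decay slows or their transcription is induced. Of 19 tested, 8 rose and 19 were positive, among them HES1 at 1.69, PPP1R15A at 1.48 and NR4A1 at 1.30, with a median of 0.85, above 100% of matched random lists both without and with Myc. That list was written after DUSP and KLF genes were seen to rise. It holds DUSP2, DUSP8, KLF2 and KLF10 of these families, of which KLF10 passed the test, so it repeats the observation in part. Its other risen members, HES1, PPP1R15A and NR4A1 among them, are of other families. The choice of list was prompted by the genes seen to rise, and footprints do not measure half-lives. The list therefore cannot decide the hypothesis. EGR1, an immediate-early gene outside the list, fell by 1.27 on the log2 scale in the averaged comparison. It was read at 29 and 19.3 FPKM in control and 4.4 FPKM with Torin-1. With Myc it was read at 34.6 and 60.6 FPKM, and at 35.8 FPKM with both, so the fall lay mainly in cells without Myc. The FOXO hypothesis was likewise drawn from genes seen to rise and was tested on the same libraries. The values leave it open without deciding it, and they cannot separate mRNA level from translation.

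The fall of ribosomal protein genes with Torin-1 (median -0.99) was set against technical explanations. If compression of abundant transcripts in the Torin-1 libraries caused the whole fall, genes of other classes at the same FPKM would fall as far. The median of 73 such genes was -0.1934 (95% bootstrap interval -0.293 to -0.163), against 0.0207 for all 9482 genes tested. The interval came from resampling genes with the libraries held fixed. It therefore leaves out the variation between libraries, that of the single Torin-1 libraries included. The 73 genes thus fell too, but by less than the ribosomal protein genes. Within these libraries this argues against compression as the whole explanation, while a part of the fall could still come from it. The median against replicate 2 alone was -1.073, so the fall did not need the replicate 1 libraries. That test was chosen after its result was seen, so it is no independent support. For this list, control replicate 2 stood above control replicate 1 by a median of 0.44. Against replicate 1 alone the medians were -0.60 without Myc and -1.13 with Myc, so the list was lower against either replicate. Reads shared with pseudogene copies were not tested, and reduced translation of these mRNAs when mTOR is inhibited, the biological explanation in the design, stays open as a hypothesis.

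The rise of ribosomal protein genes with Myc was larger in the replicate 1 pair than in the replicate 2 pair by a median of 0.61. A dependence on abundance could account for part of it: 73 genes of other classes at the same FPKM differed between the pairs by 0.3351 (95% bootstrap interval 0.197 to 0.435). That interval also came from resampling genes with the libraries held fixed. It holds the value set in advance to decide, 50% of the ribosomal protein difference. A dependence on abundance therefore cannot be told apart from an explanation particular to ribosomal protein genes.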
